A study of Mus musculus with 86 samples.

How the data were processed

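Peak lists of 8 ChIP-seq libraries of mouse embryonic stem cells were used: SOX2 (antibody AF2018) and CTCF (antibody ab70303), each in 2 asynchronous and 2 mitotic libraries. Groups were taken from the sample titles and treatments. Per the submitters' processing notes, CASAVA 1.4, BWA 0.7.17, SAMtools and MACS2 2.1.1.20160309 were used with the genome build mm10. Their roles and options, the filters and the choice of control library are not given in the sources used here. The authors deposited 1 narrowPeak list per library, so replicates were not pooled. In each list the deposited fold enrichment is a ratio of the coverage at the peak summit to a local background, and the deposited −log10 p-value and −log10 q-value belong to the same summit. The lowest −log10 q of each list lay between 1.31 and 1.48, which puts the threshold of the calls at a q of 0.05. Fold and −log10 p are the authors' values and were used only to rank, filter or describe peaks within their own list.

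A change of coverage between conditions cannot be read from lists called separately, so conditions were compared by which regions were called. Depth was estimated from the lists. MACS2's fold and −log10 p at a summit follow from the coverage and the local background under a Poisson model, so both were solved for in up to 2000 peaks per library. Whole-number coverage, within 0.002 reads, came out for 95.6% to 100% of the peaks solved. The lowest local background, 2.92 to 7.81 reads, is the genome-wide average coverage. Dividing it by the shortest peak width (178 to 219 bp), which MACS2 sets by default to its fragment length, gave a depth per 100 bp that can be compared between libraries. All lists held peaks on the 21 standard chromosomes only.

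The overlapping peaks of both asynchronous libraries of a factor were merged, and merged regions with a peak in each library were kept as reproducible regions. A region was called in a mitotic library if it shared at least 1 bp with a peak. Mitotic peaks were placed 100 times at random on their own chromosomes for the chance level. Strength was the percentile of a region's highest fold in each asynchronous list, averaged over both. Peak numbers and mean shares were compared by a two-sided exact permutation test, strength by a two-sided permutation test over regions with 100000 resamples, and features by two-sided Fisher's exact tests over regions called in both mitotic libraries against neither. The gene list tests instead set regions called in both mitotic libraries against all others. With 1 mitotic library alone, regions called in it were set against those not called in it. Intervals of shares are Wilson intervals at 95% confidence, and those of odds ratios come from the log odds ratio. Odds ratios at equal strength and width are Mantel-Haenszel values over 10 by 10 classes. The 26 gene list tests were adjusted together by the Benjamini-Hochberg method.

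Gene names and positions came from a table of RefSeq genes on GRCm38.p6, the assembly of mm10, with 49943 genes on these chromosomes, of which 21887 are protein-coding and 408 are tRNA genes. The table has no strand, so the planned promoter comparison was replaced by gene ends, within 1 kb of either boundary of a protein-coding gene. Genes were assigned by the distance to the gene body, up to 50 kb, in place of the distance to the start of transcription. The planned motif comparison was not run, since no genome sequence was used here. Of the 10 X inactivation center genes asked for, Linx and Xite had no match. The other lists matched in full.

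Regions and genes to be named were fixed before the data were examined: per factor the 10 strongest regions called in both mitotic libraries, the 10 strongest called in neither, up to 5 strongest regions called in both mitotic and no asynchronous library, and up to 15 genes of the pluripotency list for SOX2 and of the imprinted, X inactivation center and cohesin, condensin and CTCF lists for CTCF. The genes at gene ends, the tRNA genes, the CTCF list genes with no region called in both mitotic libraries and the genes named beside a list's count, such as Gata6 and Gnas, were picked after their values were seen.

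Alternatives were a −log10 q of at least 5, a fold of at least 5, all sequences in the lists, an overlap of 50% of the shorter interval, summits within 100 bp, regions of either asynchronous library, leaving out each library, comparing libraries of the same replicate number, strength classes, the strongest 10% of regions, and gene distances of 10 and 100 kb. Chosen after the data were seen were a gene-end window of 2.5 kb, the summit at the gene end, strength and width classes, the same classes with −log10 p in place of fold, regions away from tRNA genes, mitotic lists at equal length, and the tRNA and X chromosome results. Permutation tests in the alternatives used 1000 resamples.

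The code was tested on simulated data. On 20142 intervals its overlap count of 4685 equalled that of bedtools. A gene-end odds ratio of 4 put into the real regions came back as 4.00 for SOX2 and 4.04 for CTCF on average, a difference of 0.3 came back as 0.299 and 0.300, and a simulated background of 5.5 reads came back as 5.5. The odds ratio check called 20.9% of SOX2 and 20.6% of CTCF regions and used strength classes only. It did not cover strength and width classes, or a share as low as the 0.675% of SOX2 regions called in both mitotic libraries. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9 and bedtools 2.31.1 were used. The 52 histone mark and 26 input libraries were not used here.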

Results

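The series covers mouse embryonic stem cells (strain 129S5/SvEvBrd), self-renewing cells derived from the early embryo, kept in serum with leukemia inhibitory factor. Chromatin immunoprecipitation with sequencing (ChIP-seq) was done on asynchronous cultures and on mitotic cells, which were arrested with 100 ng/ml of the microtubule poison nocodazole for 6 h and shaken off the dish. Peak lists from 8 of the 86 libraries were analysed here. They cover SOX2, an HMG-box transcription factor of the pluripotency network, and CTCF, a zinc finger protein that marks chromatin loop anchors and insulators. Each factor has 2 asynchronous and 2 mitotic libraries, and each list was called by itself. The 52 histone mark and 26 input libraries were not analysed here. The labels do not say that the replicates came from separate cultures, so the spread between them may be technical.

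The asynchronous SOX2 lists held 90266 and 63504 peaks for replicates 1 and 2, and the mitotic SOX2 lists 1976 and 408. The asynchronous CTCF lists held 68328 and 67995 peaks, and the mitotic CTCF lists 20142 and 15338. The read totals were not used here, but a relative depth could be read from the lists. It is the background coverage of each library per 100 bp of its shortest peak, a width that MACS2 sets by default to the fragment length. This depth was 2.48 and 1.61 for asynchronous SOX2, 2.62 and 1.64 for mitotic SOX2, 3.36 and 3.72 for asynchronous CTCF, and 3.62 and 3.77 for mitotic CTCF. By this measure the mitotic libraries were as deep as the asynchronous libraries of the same number, with ratios of 1.05 and 1.02 for SOX2 and 1.08 and 1.02 for CTCF. Replicate lists of asynchronous CTCF overlapped by 86.8% and 86.9% of their peaks. Those of asynchronous SOX2 overlapped by 58.8% and 87.6%, those of mitotic SOX2 by 18.2% and 88.2%, and those of mitotic CTCF by 72.2% and 95.8%.

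**Figure D1:**
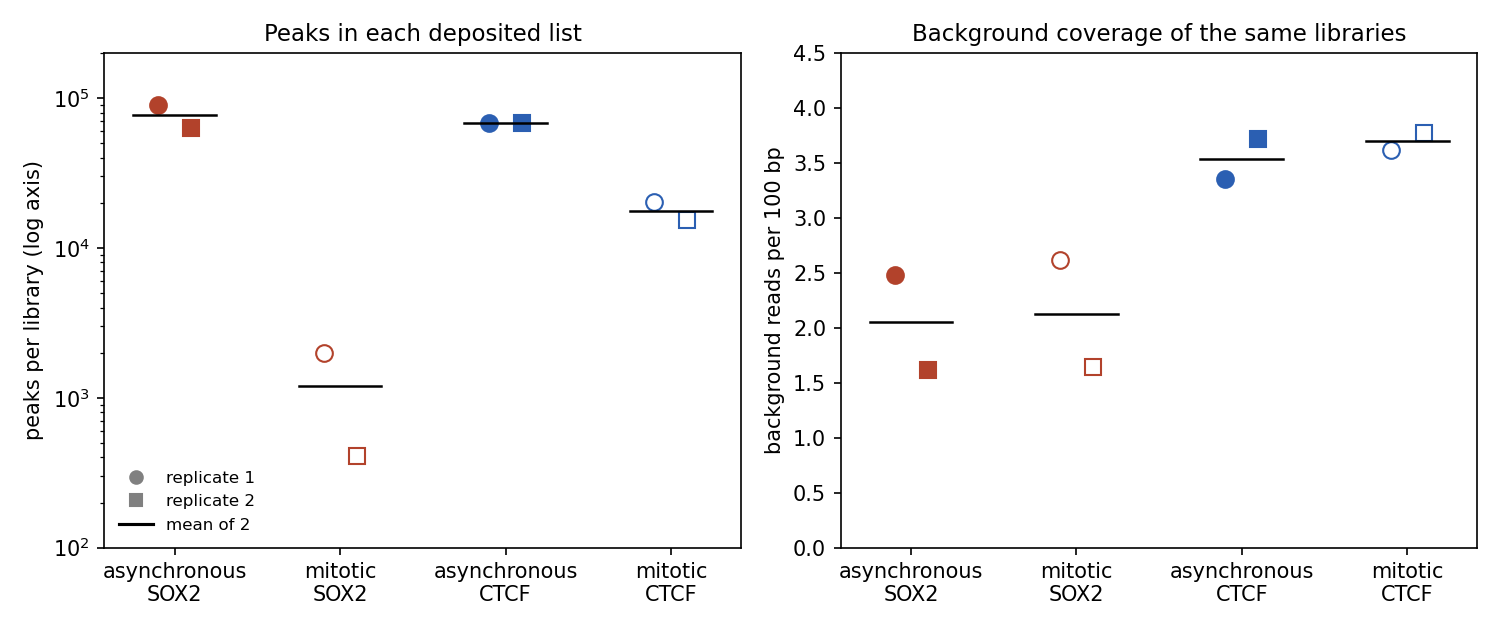
Peaks per library (left, log axis) and background reads per 100 bp of the shortest peak (right) for the 4 groups, with filled symbols for asynchronous and open symbols for mitotic libraries, circles and squares for replicates 1 and 2, and a black line at the mean of 2. The mitotic SOX2 lists held 1976 and 408 peaks, while their background coverage of 2.62 and 1.64 lay close to the 2.48 and 1.61 of the asynchronous libraries.

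The first comparison asks how much of the SOX2 binding seen in cycling cells is detected in mitosis. Few SOX2 peaks were called in mitotic cells: 1192 ± 1109 (SD, n = 2) against 76885 ± 18924 (SD, n = 2) in asynchronous cells, or 64.5-fold fewer. Of 51672 SOX2 regions found in both asynchronous libraries, mitotic replicate 1 called 1740 (3.37%, 95% Wilson interval 3.22 to 3.53) and replicate 2 called 390 (0.755%, 0.684 to 0.833). Their mean was 2.06% ± 1.85 (SD, n = 2), where random placement of the mitotic peaks gave 0.0972% and 0.0188%. Both mitotic libraries called 349 regions, 1 library alone called 1432, and 49891 (96.6%) were called in neither. The mitotic SOX2 peaks were almost entirely a subset of the asynchronous peaks, with 99.2% ± 0.793 (SD, n = 2) inside them against 3.83% and 3.54% at random. The only region called in both mitotic libraries and in no asynchronous library (7:12011535-12011755, mm10) lay 29.5 kb from Vmn1r77, a vomeronasal receptor gene.

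SOX2 regions around pluripotency genes were mostly absent from the mitotic lists, as were SOX2 regions in general, of which 96.6% were called in neither library. The absence was not particular to these genes. Of the regions nearest to them 1.26% were called in both mitotic libraries, against 0.721% of other regions (odds ratio 1.75, 0.557 to 5.49). All 30 pluripotency genes of a list fixed before the data were examined had asynchronous SOX2 regions within 50 kb. For 3 of them (Pou5f1, Lin28a and Phc1) a region was called in both mitotic libraries, for 13 a region was called in 1 library, and 14 had none called. Pou5f1, which encodes OCT4, the partner of SOX2 on DNA, had 15 regions, of which both mitotic libraries called 1 and 12 were called in neither. The called region (17:35503555-35506385, mm10) reached from outside Pou5f1 into the gene, and its peaks had fold enrichments, as given by the authors, of 26.9 and 34.0 in the asynchronous lists. The mitotic peaks there were shorter, 35503858-35504306 in replicate 1 and 35503994-35504173 in replicate 2, and lay outside the annotated gene (17:35506032-35510777). Lin28a, encoding an RNA-binding protein that blocks let-7 maturation, had 1 of 10 regions called in both libraries, and Phc1, encoding a Polycomb component, 1 of 7. None of the 14 regions near Sox2 itself, the 14 near Nanog, the 16 near Esrrb, the 33 near Jarid2 or the 18 near Fgf4 was called in both, and those near Klf5, Zfp42, Dppa3 and Prdm14 were called in neither library.

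**Figure D2:**
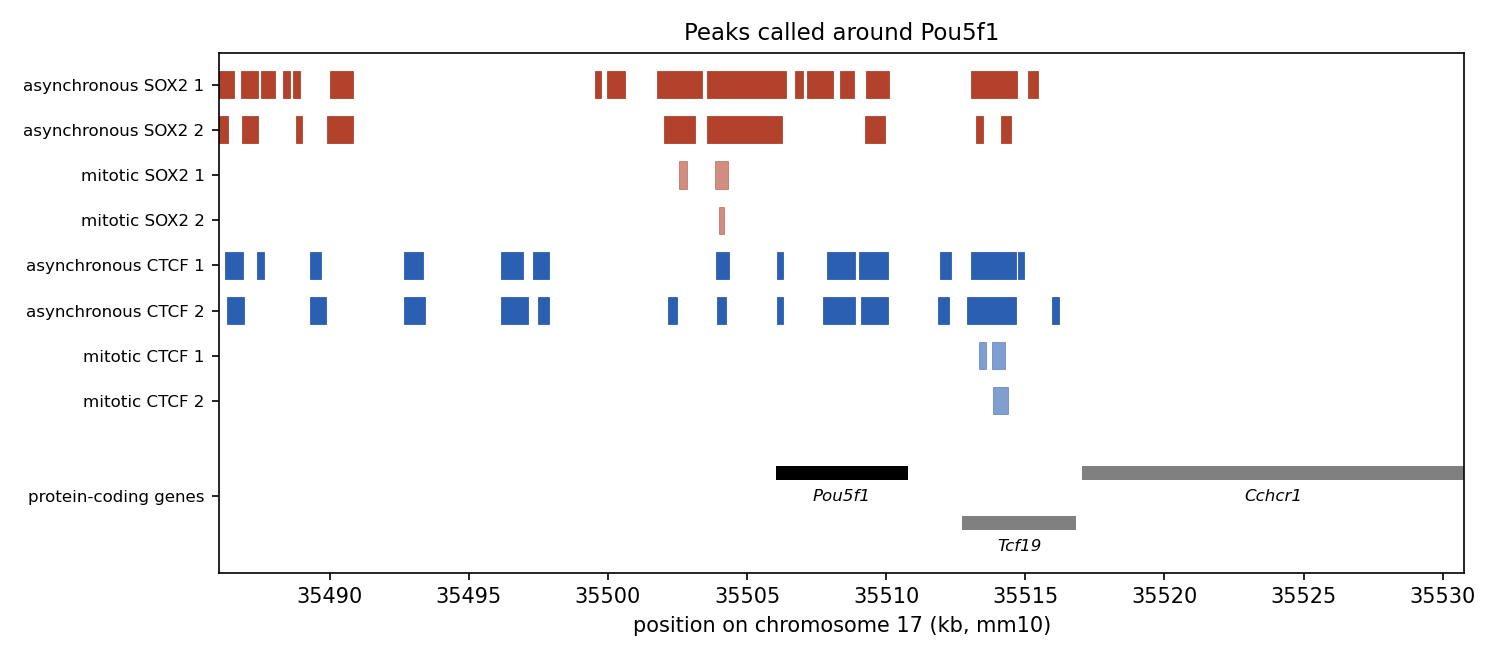
Peaks called in each of the 8 libraries (1 line per library, boxes to scale) along chromosome 17 around Pou5f1 (black) and neighbouring protein-coding genes (grey), with the position in kb on mm10. The mitotic SOX2 peaks at 35503858-35504306 and 35503994-35504173 lie within the strongest asynchronous SOX2 peaks of the window, and mitotic CTCF peaks appear over Tcf19.

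The SOX2 regions called in mitosis came mainly from the strongest asynchronous regions, but most of the strongest were not called. Regions called in both mitotic libraries had a median strength percentile of 94.5, ranked by fold within each asynchronous list, against 60.4 for those called in neither. The strongest of them lay within Prune2 (19:17137392-17139007, folds 51.8 and 50.3), within Trdn, which encodes triadin of the muscle calcium release complex, 1.75 kb from Txlng and 107 kb from Ahr, the aryl hydrocarbon receptor gene. Others had Tprg, Loxl1, Smgc, Lrig1, Zfp804a and AB010352 as the nearest gene. Regions of like strength were called in neither mitotic library within Tox (4:6968544-6969476, folds 51.9 and 45.8), Aak1, Ctnna3, Tnfsf11, Rims1, Sptlc2 and the overlapping Tsix and Xist, the antisense pair that controls X inactivation (X:103471934-103473131, folds 51.1 and 41.8). The others of the strongest 10 lay at Ak3 and Cdc37l1 or had Diaph3 and Cxadr as the nearest gene. In the top 1% of SOX2 regions, 59 of 516 (11.4%) were called in both mitotic libraries and 390 (75.6%) in neither.

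The peak numbers differed in the same direction in all libraries, and the exact permutation test of 2 against 2 gave p = 0.333, the smallest it can give. The strength difference of 34.1 percentile points had a permutation p of 1e-05, the smallest that 100000 resamples can give. Tests over regions are not tests over replicates, and their intervals cover counting error only. The mitotic libraries differed: the ratio of mitotic to asynchronous peaks was 0.0155, 0.00531 without mitotic replicate 1 and 0.0257 without mitotic replicate 2. The mean share of regions called was 3.37% without mitotic replicate 2, 0.755% without mitotic replicate 1 and 1.21% without asynchronous replicate 2. It was 1.29% among peaks with a fold of at least 5, 1.13% over the regions of either asynchronous library and 0.767% with the longer mitotic list shortened to its strongest 408 peaks.

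CTCF, measured in the same design, kept many more called regions in mitosis. CTCF peaks numbered 17740 ± 3397 (SD, n = 2) in mitotic cells against 68162 ± 235 (SD, n = 2) in asynchronous cells, or 3.84-fold fewer. Of 57992 CTCF regions found in both asynchronous libraries, the mitotic libraries called 33.0% (32.6 to 33.4) and 25.4% (25.1 to 25.8), a mean of 29.2% ± 5.36 (SD, n = 2), against 1.00% and 0.716% at random. Both libraries called 14210 regions, 1 library alone called 5491 and 38291 were called in neither. As for SOX2, the mitotic CTCF peaks were a subset, with 99.4% ± 0.443 (SD, n = 2) inside asynchronous peaks against 3.40% and 3.19% at random. CTCF regions called in both mitotic libraries and in no asynchronous library numbered 17, with the strongest at or near Asb1, Rab11a, Tbc1d31, Shf and, on the Y chromosome, Gm52481.

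Among the strongest CTCF regions, calling in mitosis was close to complete. All of the 50 strongest CTCF regions were called in both mitotic libraries, as were 529 of the top 579 (91.4%), and 17 of these were called in neither. The strongest lay within Coa5 (1:37418856-37420474, folds 41.2 and 40.9), Rtkn2, Cdsn, Map3k15 (X:159987640-159988756, folds 45.9 and 34.9), Cfap57, C1qtnf9, the overlapping A430057M04Rik and Comtd1, Top1mt, the gene of mitochondrial topoisomerase I, and Ctif, and 1.29 kb from Nemp1. The strongest regions called in neither lay within Speg (1:75413411-75414573, folds 34.1 and 21.3), Fbln1, Cfap45 and Map7 or had Gucy2f, Gm4131, Necap2, Snx6, Robo1 or, at 580 kb, Dad1 as the nearest gene. Regions called in both had a median strength percentile of 84.3 against 43.1 for those called in neither, and they were wider, at 903 bp against 491 bp.

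The share of CTCF regions called in both mitotic libraries differed from gene to gene at architectural and imprinted genes, on few regions each. Over all CTCF regions it was 24.5%, and whether the genes vary beyond what such small counts give was not tested. Overlapping or neighbouring genes, such as Gnas and Gnasas1 or Tsix and Xist, can share regions, so the genes counted below are not separate cases. Within 50 kb of Ctcfl, the germline paralog of Ctcf, 5 of 12 regions were called in both mitotic libraries, and near Ctcf itself 5 of 11. Of 19 cohesin, condensin and CTCF genes with regions, 12 had a region called in both, such as the cohesin genes Stag1 (3 of 10) and Smc3 (2 of 9) and the cohesin loader gene Nipbl (1 of 9). The other 7 had none called in both, among them Mau2 (0 of 10), Ncaph (0 of 9), Smc4 (0 of 8) and Rad21 (0 of 4). Of these 7, 3 had a region called in 1 mitotic library and 4 had none called. Of 19 imprinted genes, 14 had a region called in both, with 5 of 7 near Cdkn1c, 3 of 8 near Usp29, 2 of 6 near Meg3, 2 of 2 near Peg10 and 1 of 6 near H19, the noncoding gene beside the CTCF-bound imprinting control of Igf2. The other 5 had none called in both: Gnas, Gnasas1 and Snrpn (0 of 8 each), Igf2 (0 of 5) and Mest (0 of 4). All 5 had a region called in 1 mitotic library. All 8 genes of the X inactivation center list had CTCF regions, and 0 had a region called in both mitotic libraries. For 4 of them a region was called in 1 library, and 4 had none called.

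For CTCF peak numbers the exact permutation test again gave p = 0.333, the smallest possible with 2 against 2. The strength difference of 41.1 percentile points had a permutation p of 1e-05, the smallest that 100000 resamples can give.

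The factors differed in how many of their regions were called in mitosis. The mean share of regions called was 27.2 percentage points higher for CTCF, with both CTCF libraries above both SOX2 libraries. In the strongest 10% of regions the shares were 85.4% ± 5.72 (SD, n = 2) for CTCF and 6.98% ± 3.68 (SD, n = 2) for SOX2. Among the 50 strongest regions, all CTCF regions and 19 SOX2 regions were called in both mitotic libraries. The exact permutation p of 0.333 for the mean shares is again the smallest that 2 against 2 allows. The antibodies differ, so the shares compare detection and not occupancy. The mitotic CTCF libraries were also deeper, with 3.62 and 3.77 background reads per 100 bp against 2.62 and 1.64 for mitotic SOX2. How far depth accounts for the difference was not tested.

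**Figure D3:**
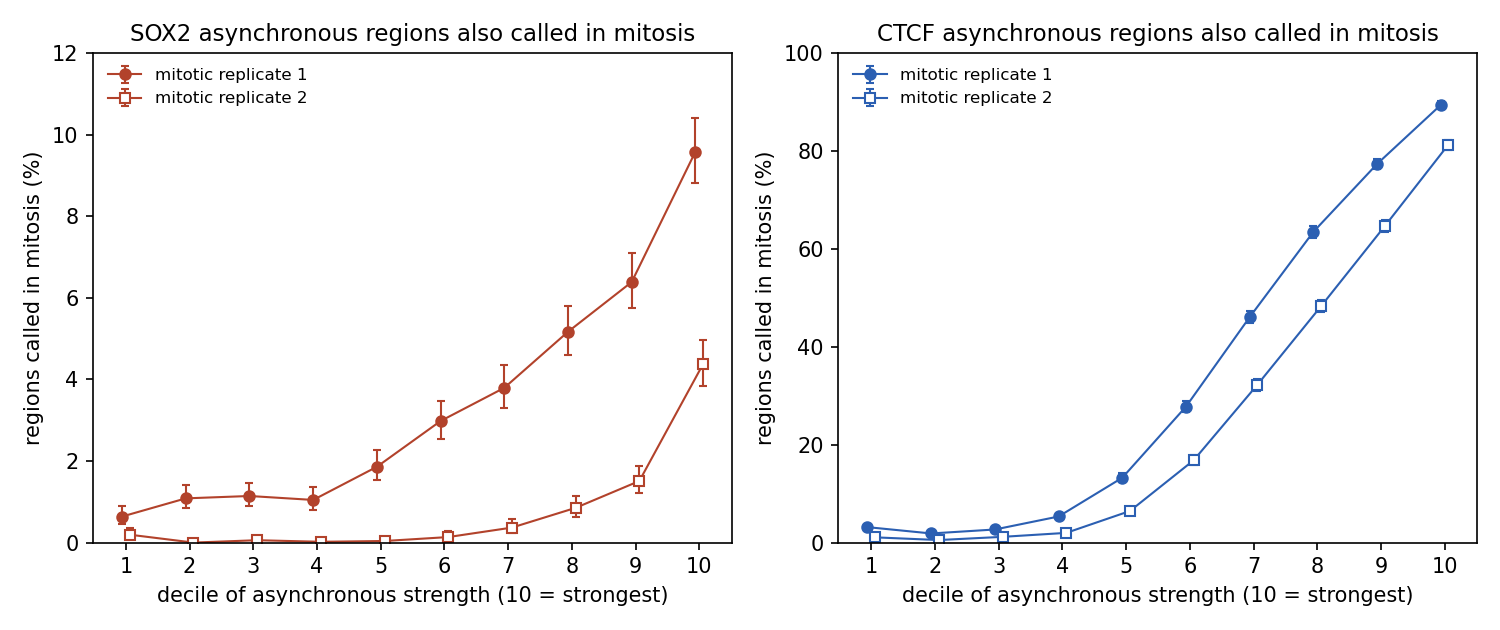
Percent of reproducible asynchronous regions called in each mitotic library, by decile of asynchronous strength (10 is the strongest), for SOX2 (left, axis to 12%) and CTCF (right, axis to 100%), with 95% Wilson intervals that cover counting error only. In decile 10 the mitotic libraries called 9.58% and 4.37% of SOX2 regions and 89.4% and 81.3% of CTCF regions.

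The SOX2 regions that were called in mitosis lay at the ends of genes far more often than the rest. Of the 349 regions called in both mitotic libraries, 169 (48.4%) lay within 1 kb of either end of a protein-coding gene, against 16.7% of those called in neither (odds ratio 4.67, 95% interval 3.78 to 5.77, Fisher's exact p = 3.81e-42). The rest of the regions called in both and in neither lay inside genes away from their ends (20.6% and 39.1%) or outside genes (30.9% and 44.2%). The strongest of the gene-end regions, picked after their values were seen, were at Mobp (9:120148821-120150365), Rif1, which encodes a regulator of replication timing, Gadd45g, Pou5f1, B3gnt7, Il17rd, Rundc3b, Map4k4, Kat7 and Pipox. Among regions of equal strength and width the odds ratio was 6.78 (5.30 to 8.69), and it was 7.84 (6.02 to 10.2) where the summit of the asynchronous peak had to lie within 1 kb of the gene end. At 136 of the 169 regions (80.5%) the summit of the strongest mitotic peak lay within 1 kb of a gene end, but not at Pou5f1, where only the asynchronous region reached it. The gene table gives no strand, so starts and ends of genes were not told apart.

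For CTCF the same feature made little difference. Of the regions called in both mitotic libraries 15.5% lay at gene ends, against 13.2% of those called in neither (odds ratio 1.21, 1.14 to 1.27, Fisher's exact p = 2.27e-11). This did not hold among regions of equal strength and width (0.934, 0.853 to 1.02, p = 0.155), nor without asynchronous CTCF replicate 1 (1.00, p = 0.863). Matching on the deposited −log10 p in place of fold turned the direction (0.732, 0.664 to 0.808). The strongest CTCF regions of this kind were at Cdsn, Map3k15, Comtd1 and Top1mt.

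SOX2 regions that overlapped a called CTCF region of asynchronous cells were called in mitosis more often. The overlap is of called peaks by at least 1 bp and no motif was checked, so binding of CTCF there is not shown. A reproducible CTCF region overlapped 193 of the 349 SOX2 regions called in both mitotic libraries (55.3%), against 19.2% of those called in neither (odds ratio 5.20, 4.21 to 6.43, Fisher's exact p = 4.46e-50). Both mitotic libraries called 2.82% of SOX2 regions with CTCF at a gene end, 1.37% of those with CTCF elsewhere, 1.23% of those at a gene end without CTCF and 0.233% of those with neither. Of the 10 strongest SOX2 regions called in both mitotic libraries, 8 overlapped CTCF in asynchronous cells, but so did 7 of the 10 strongest called in neither, so these examples show no difference. Of the 8, both mitotic CTCF libraries had a peak at those nearest to Loxl1 and Lrig1, and neither had one at those of Prune2, Ahr, Trdn, Tprg, Smgc and AB010352. The odds ratio fell to 3.63 (2.91 to 4.53) at equal strength and width, to 3.01 among peaks with a fold of at least 5 and to 3.10 where summits had to lie within 100 bp.

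In the other direction, SOX2 overlapped 23.2% of the CTCF regions called in both mitotic libraries and 16.0% of those called in neither (odds ratio 1.59, 1.52 to 1.67, Fisher's exact p = 9.96e-79). The direction was not settled: the odds ratio was 1.11 (1.03 to 1.2) at equal strength and width, 1.05 (0.973 to 1.14, p = 0.207) when regions near tRNA genes were also left out, and 0.842 (0.775 to 0.914) at equal −log10 p and width.

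**Figure D4:**
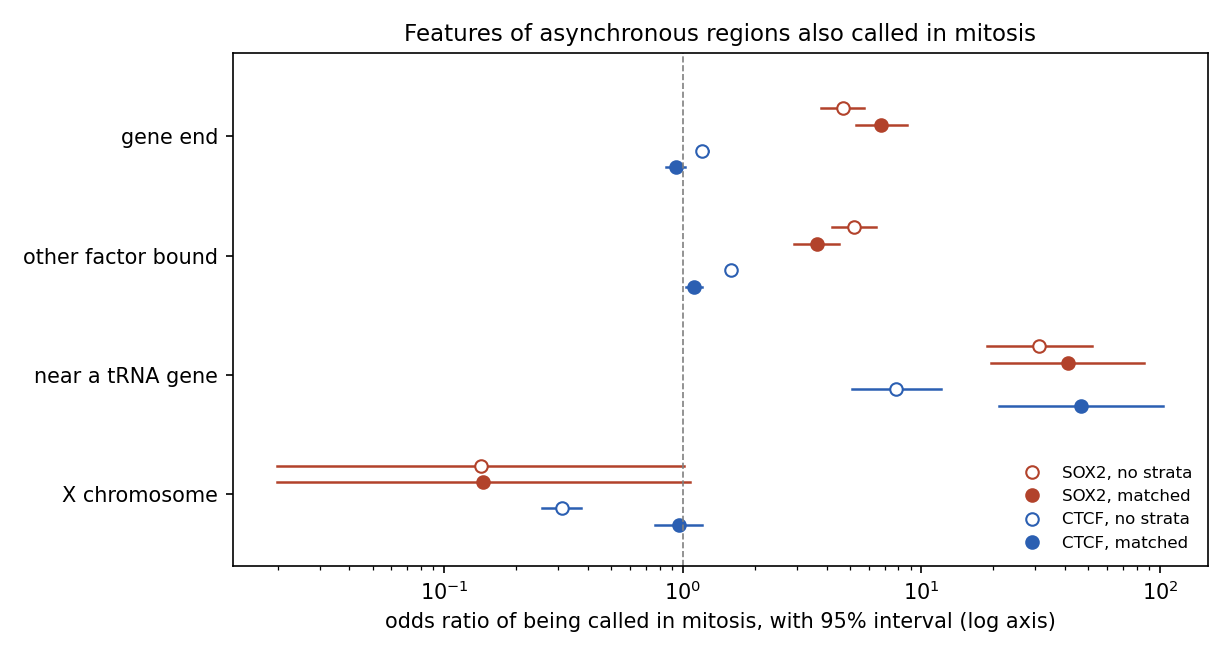
Odds ratio (log axis) of a region being called in both mitotic libraries against neither, for SOX2 and CTCF regions at a gene end, overlapping the other factor, near a tRNA gene or on the X chromosome, with 95% intervals over regions that cover counting error only. Open symbols use all regions and filled symbols compare regions in the same strength and width decile, where the gene-end odds ratio was 6.78 for SOX2 and 0.934 for CTCF.

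No gene list stood apart after correction. Over 13 lists and both factors, 26 Fisher's exact tests gave 0 lists with a Benjamini-Hochberg adjusted p under 0.05, and 4 with an unadjusted p under 0.05, all for CTCF. CTCF regions nearest to X inactivation center genes were called in both mitotic libraries in 0 of 22 cases (p = 0.00446, adjusted p = 0.116), against 24.5% of other regions, but of all CTCF regions on the X chromosome only 9.43% were called in both. The share was 56 of 172 (32.6%, odds ratio 1.49, adjusted p = 0.214) for ribosomal protein genes, 17 of 42 (40.5%, odds ratio 2.09, adjusted p = 0.252) for mesoderm and endoderm genes such as Gata6, Sox17 and Eomes, and 10 of 71 (14.1%, odds ratio 0.504, adjusted p = 0.252) for Polycomb and trithorax genes. It was 16 of 43 for Hox clusters, 24 of 82 for clustered protocadherins, 25 of 144 for pluripotency genes, 11 of 61 for imprinted genes, 12 of 57 for cohesin, condensin and CTCF genes, 12 of 66 for mitosis and cell cycle genes, 10 of 49 for neuroectoderm, 12 of 39 for trophoblast and 11 of 48 for core histones.

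For SOX2, 3 of 239 regions nearest to pluripotency genes were called in both mitotic libraries (1.26%, against 0.721% of other regions, odds ratio 1.75, 0.557 to 5.49, adjusted p = 0.691). Imprinted genes had 2 of 68, at Cdkn1c and Gnas, and Stag1, Hoxb1 and H4c8 gave 1 each among the 59 cohesin, condensin and CTCF, 86 Hox and 64 core histone regions. The counts were 0 of 79 for neuroectoderm, 0 of 45 for mesoderm and endoderm, 0 of 49 for trophoblast, 0 of 95 for Polycomb and trithorax, 0 of 69 for mitosis and cell cycle, 0 of 23 for X inactivation center, 0 of 61 for protocadherin and 0 of 131 for ribosomal protein genes. With so few SOX2 regions called in mitosis, these tests could miss differences of the size that the interval for pluripotency genes allows.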

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

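All tests in this part were chosen after the results were seen. At equal strength and width, the odds ratio of being called in mitosis at gene ends was 7.26 times as high for SOX2 as for CTCF (95% interval 5.58 to 9.45, z test of the log odds ratios, adjusted p = 1.65e-48 over 4 features), which made it stand out as a difference between the factors. The odds ratio for overlapping a region of the other factor was 3.27 times as high for SOX2 (2.59 to 4.14, adjusted p = 8.53e-23). The regions of the factors are partly shared (20.3% of SOX2 and 18.3% of CTCF regions overlap the other factor), so these values are not fully independent.

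For the gene-end pattern, stronger or wider regions at gene ends as the source would leave no difference among regions of equal strength and width, yet the odds ratio there was 6.78 (5.30 to 8.69), and 7.44 (5.84 to 9.48) with −log10 p in place of fold. A signal that mitotic chromatin gives at gene ends with any antibody would appear with CTCF too. Of the 169 regions, 41 (24.3%, 18.4 to 31.2) were called in at least 1 mitotic CTCF library. That is fewer than such a signal would give as the whole source if both antibodies detected it equally well, which was not tested. A missing call does not show missing signal, so how much of the pattern it could account for, beyond those 41, stays open. A biological source, such as SOX2 kept at gene ends in mitosis or chromatin there that stays accessible, may remain. Gene-end regions called in neither mitotic SOX2 library were less often called in a mitotic CTCF library (13.8%) and less often had an asynchronous CTCF peak (47.3% against 79.9%), which goes with a signal shared between the antibodies at part of the regions, but the 180 regions called away from gene ends had like shares (26.7% and 72.2%). These data do not separate the binding of SOX2 itself from accessibility, and the histone mark libraries were not analysed here.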

How the results depend on the processing

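For 23 results 202 alternatives were run. Of the 100 with a test over regions 89 kept the direction and the side of the threshold, but 6 of these used all sequences, which changes nothing since the lists hold the standard chromosomes only. Leaving out 1 of 2 mitotic libraries always moves a mean share by less than the SD, so the SOX2 share of 2.06%, which became 0.755% or 3.37%, is not shown to be stable. With n = 2 the exact permutation tests cannot pass 0.05, so stability refers to values and to tests over regions. The SOX2 gene-end odds ratio stayed between 3.81 and 11.4, that of SOX2 with CTCF between 3.01 and 7.33, and the 0 gene lists past correction stayed at 0 in every alternative run. The shares of regions called with peaks of a −log10 q of at least 5 were 1.68% for SOX2 and 29.6% for CTCF. The settings with strength and width or −log10 p classes, the gene-end summit, and the X chromosome and tRNA values were chosen after the data were seen. Some of the values that changed follow, and their causes were not tested except where the setting itself shows it. With a fold of at least 5 the SOX2 peak ratio was 0.0103 (main 0.0155) and the overlap of asynchronous CTCF replicates 89.4% (main 86.9%). That overlap was 89.2% with a −log10 q of at least 5, 85.8% with an overlap of 50% and 80.8% with summits within 100 bp. Other mean overlaps of replicates fell further. With summits within 100 bp they were 55.3% for asynchronous SOX2 (main 73.2%) and 41.3% for mitotic SOX2 (main 53.2%). With a fold of at least 5 that of mitotic CTCF was 77.3% (main 84.0%). These falls counted as no change, since the limit was the SD of the 2 overlap directions, which is wide where list lengths differ. With summits within 100 bp, 74.5% of SOX2 and 94.4% of CTCF mitotic peaks lay at asynchronous ones. Over regions of either asynchronous library, which adds weak regions, CTCF had 22.5% called and exceeded SOX2 by 21.4 points, and in the strongest 10% by 78.4 points. The CTCF gene-end odds ratio was 0.934 in strength and width classes, 0.933 without regions near tRNA genes, 0.732 in −log10 p and width classes, and 1.02 with the summit at the gene end. CTCF with SOX2 gave 1.05 without regions near tRNA genes and 0.842 in −log10 p and width classes. The tRNA odds ratios (main 41.1 for SOX2, 46.7 for CTCF) were 31.2 and 7.83 with no classes, and 49.3 and 40.5 with −log10 p. In a mitotic library alone they were 15.6 and 16.6 for SOX2 and 29.5 and 18.7 for CTCF. There the comparison changed too, from called in both against neither to called against not called. For regions overlapping the tRNA gene itself they were 41.3 for SOX2 and 102 for CTCF. The CTCF X chromosome odds ratio was 0.310 with no classes, 1.45 with −log10 p, 1.25 in mitotic library 1 alone and 0.776 in mitotic library 2 alone, so it has no settled direction. Leaving out each library gave SOX2 peak ratios of 0.00531 to 0.0257, SOX2 mitotic peaks inside asynchronous ones of 97.0% to 99.8%, CTCF 98.9% to 99.7%, and CTCF gene-end odds ratios of 1.00 to 1.27. Replicates share only a number, which the labels tie to no batch. With the number as a replicate block, the SOX2 peak ratio was 0.0119, the CTCF peak ratio 0.258, and the shares called 1.3% and 25.2%. The 2 strength differences, the results with a test that were run under the block, kept their calls. The promoter and motif comparisons were not run, for want of strand and sequence. With 349 SOX2 regions called in both mitotic libraries the gene list intervals are wide, 0.557 to 5.49 for pluripotency genes. How read depth limits the calls was not tested, since only relative depth was estimated.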

Other observations

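The tests in this part were chosen after the results were seen, except the comparison of tRNA regions between the antibodies, which was chosen before its result was seen. SOX2 and CTCF regions within 500 bp of tRNA genes, which RNA polymerase III transcribes, were called in mitosis more often than other regions. For SOX2, 19 of 183 such regions (10.4%, 6.75 to 15.6) were called in both mitotic libraries against 0.641% elsewhere, and for CTCF 81 of 130 (62.3%, 53.7 to 70.2) against 24.4%, although the CTCF regions near tRNA genes were weak, with a median strength percentile of 25.5. Of the 168 tRNA genes close to a CTCF region, 125 were close to one called in both mitotic libraries, and of the 255 close to a SOX2 region, 39. The strongest SOX2 region of this kind lay at the arginine tRNA gene n-TRtct5 (1:173389453-173390628), and n-TLaag4 on chromosome 7 was among the strongest 10 of both factors (SOX2 7:120917253-120918771, CTCF 7:120917334-120918267).

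SOX2 regions on the X chromosome were called less often than those on autosomes, though on few calls. On the X chromosome 1 of 997 SOX2 regions (0.100%) was called in both mitotic libraries, the region near Txlng, against 0.687% on autosomes (odds ratio at equal strength and width 0.146, 0.0199 to 1.07, p = 0.0294). The odds ratio was 0.263 (0.123 to 0.561, p = 0.000215) in mitotic library 1 alone, 0.140 (0.0192 to 1.03, p = 0.0253) in library 2 alone, 0.142 (p = 0.0178) with no classes and 0.155 (p = 0.0372) with −log10 p, none adjusted for the choice of this chromosome. For CTCF it was 122 of 1294 (9.43%) against 24.8%, but the odds ratio at equal strength and width was 0.959 (0.764 to 1.2, p = 0.702), and its direction was not settled. The factors did not differ in this odds ratio past the threshold (adjusted p = 0.0873). On the Y chromosome 13 of 23 CTCF and 0 of 5 SOX2 regions were called in both, which was not tested. The SOX2 regions on the X chromosome had a median strength percentile of 73.6, against 61.0 on autosomes. Coverage of the X chromosome and its number of copies in these cells were not examined, so fewer calls there need not mean a loss of SOX2 in mitosis.

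Regions near tRNA genes may carry a signal that mitotic chromatin gives with any antibody. If so, the same regions should be called with both antibodies, and 14 of the 19 SOX2 regions (73.7%, 51.2 to 88.2) were also called in both mitotic CTCF libraries, against 32 of 92 (34.8%) of those called in neither mitotic SOX2 library. The sharing is not particular to mitotic chromatin, since 15 of the 19 (78.9%) overlapped a reproducible asynchronous CTCF region and 118 of the 130 CTCF regions near tRNA genes (90.8%) an asynchronous SOX2 region. In the other direction the prediction was not met. Of the 81 CTCF regions called in both mitotic CTCF libraries, 12 (14.8%, 8.68 to 24.1) were called in both mitotic SOX2 libraries. Among those called in neither mitotic CTCF library it was 0 of 28. The mitotic SOX2 libraries called few regions of any kind, so this direction does not decide the question. Stronger or wider regions near tRNA genes are argued against, since the lower of the odds ratios at equal strength and width was 41.1 (SOX2, 19.6 to 86.1; CTCF 46.7, 21.1 to 103), though in a mitotic library alone it was 15.6 and 16.6 for SOX2 and 29.5 and 18.7 for CTCF. Reads shared between tRNA gene copies were not tested, and a retention of both factors at tRNA genes stays open as well, with no difference between the factors past the threshold (ratio of odds ratios 0.880, adjusted p = 0.817).

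The small number of mitotic SOX2 peaks was weighed in the same way. Fewer reads are argued against: the ratios of mitotic to asynchronous background coverage were 1.05 and 1.02 per 100 bp of the shortest peak, and 1.01 and 0.834 before the division by that width, beside 45.7-fold and 156-fold fewer peaks. The signal could be lowered alike at every region, as by asynchronous cells left in the harvest or by a poorer precipitation. That alone would give no difference between regions of equal strength and width if these fixed all that decides a call. The gene-end odds ratio there was 6.78, and 7.44 with −log10 p in place of fold. Neither matching holds fold and local background fixed together, and at equal fold a higher background means more reads. The odds ratio argues against such a lowering as the sole source of which regions were called only if local background was alike. Whether it was alike at gene ends and elsewhere was not tested. The odds ratio cannot tell why 96.6% of SOX2 regions were called in neither library, since only 1.81% of gene-end regions were called in both. The lowering thus stays open as the main source of the small number of peaks and as the source of the 180 regions called away from gene ends. A poorer precipitation together with SOX2 kept at gene ends was not excluded. Loss of SOX2 from mitotic chromosomes, in the cells or during cross-linking, stays open and was not tested, as does a direct effect of nocodazole.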
